A study of Mus musculus with 2 samples.

How the data were processed

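RNA was measured in hindlimb skeletal muscle of male C57BL/6J mice fed standard chow, with 1 microarray for wild-type mice and 1 for mice that carry a Syn4 (syntaxin 4) overexpression transgene. Per the labels' protocols, muscle was frozen in liquid nitrogen, total RNA was extracted with a Qiagen kit, and biotin-labelled whole-transcript target was made with Ambion and Affymetrix kits. The labels do not say how many mice stand behind each array, whether RNA was pooled, or how old the mice were.

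The deposited table holds log2 intensities of 35556 probe sets on both arrays, to 2 decimals. Per the submitters' processing notes, the authors used RMA in Partek. Their versions, and the steps that were run, are not given in the sources used here. RMA usually means background correction, quantile normalization across arrays and a robust summary of each probe set. The median was 6.06 in both arrays and the sorted values of the arrays differed by at most 0.14, so the arrays were on a common scale although not identical in distribution. No scanner intensities were used here, and the number of arrays limits the precision of each value. RMA compresses large ratios, so fold differences may be understated, and it gives no call of whether a probe set lies above background. For orientation, the 95th percentile of 1027 olfactory receptor genes was 5.42.

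Gene names came from the platform annotation, which can be old. Of the probe sets, 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which held 21698 of the 21789 and changed no symbol. The probe sets with 1 symbol gave 19938 genes. For the 999 genes with over 1 probe set, the probe set with the highest mean of both arrays was used. The build of the array design is not given in the sources used here, so no coordinates are reported, and the table was used only for chromosome and gene order.

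With 1 array per group there is no estimate of the spread between mice, so the difference between the genotypes was not tested and no p-value, SD or standard error is given. Bootstrap intervals over genes (10000 draws) and random placements of the differences along chromosomes, used for patterns within these arrays, take genes as the unit and do not cover the spread between mice. Each difference is the log2 intensity in the transgenic array minus that in the wild-type array, on the values as deposited. Genes were kept for counts when the higher of both values was at or above the median of that higher value over all genes, 6.79, which left 9974. A difference of 1.5-fold (0.58 on the log2 scale) was the rule of size. As a description, each gene's size of difference was ranked among itself and the 500 genes nearest in mean level, and the local spread is 1.4826 times the median absolute deviation of those 500. It mixes technical and biological variation between these 2 arrays and does not stand in for replicates.

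Of the gene lists, 22 pathway lists and 13 lists of cell type markers were written before the data were examined, as were the rule of size, the rule for named genes and the alternatives. For each list the median difference over all its measured genes was set against the medians of 10000 random lists of the same size, drawn from 20 bins of equal gene number so that levels matched. A median at or below percentile 2.5 or at or above percentile 97.5 is said to stand apart. This describes these 2 arrays and is not a test, since genes of a pathway vary together. Chance would place 1.75 of 35 lists outside those limits if genes varied independently. The text names Stx4a, the 15 genes with the largest positive and the 15 with the largest negative difference (leaving out unnamed gene models and large multigene families), list members that differed by 1.5-fold, the highest and lowest members of each list, and genes that check the sex of the mice. Any other gene named was chosen after its values were seen, and is said to be.

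The alternatives were no level filter, a filter at the olfactory receptor percentile, a filter on both arrays, a 2-fold threshold, averaged probe sets, genes with 1 probe set only, median centring, removal of a loess trend (span 0.3, 3 robustifying iterations), repeated quantile normalization, list means, unmatched random lists, and ranking by the difference over the local spread. One alternative, leaving out genes that another list also holds, was added after seeing the data. The counting and list steps were tested on simulated differences of the 9974 genes. These were the observed differences limited to just under 1.5-fold, shuffled within level bins and given random signs, so that no unchanged gene could pass the rule of size and the simulation says nothing about false calls. Among 200 genes changed by known amounts, 98% of those lowered and 96% of those raised by 1 log2 unit were counted in the right direction. All of those changed by 1.5 log2 units (100%) were counted, which the limit on the differences made certain beforehand. Of 200 unchanged lists of 20 genes, 4.5% stood apart from their matched random lists. Both kinds of list were drawn from the same shuffled differences, so a rate of about this size followed from the setting. Genes that vary together were not simulated, so the rate for real lists is unknown. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.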

Results

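Gene expression was profiled in hindlimb skeletal muscle of male C57BL/6J mice that carry a Syn4 transgene and of wild-type mice, on 1 whole-transcript array per genotype. Syntaxin 4 is a plasma membrane SNARE protein through which vesicles carrying the glucose transporter GLUT4 fuse with the muscle cell surface. The series concerns the lifespan and insulin sensitivity of these mice, and the comparison asks which muscle transcripts differ between the genotypes. Values are log2 intensities after RMA as deposited, and every difference is transgenic minus wild type. There was no replication: each value below is a single measurement with no error, and no difference has been checked against the spread between mice.

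The transgene's own gene had the second largest positive difference of all named genes. Stx4a, represented by 1 probe set on chromosome 7, had a log2 intensity of 12.20 in the transgenic array and 8.84 in the wild-type array. The difference of 3.36 corresponds to a 10.3-fold higher level. It ranked first in size among the 501 genes of like level, whose local spread was 0.22. The array labelled transgenic therefore carried the higher Stx4a signal. The species of the transgene's sequence is not given in the sources used here, so how fully the mouse probe set reads it is unknown. The nearest measured genes on either side of Stx4a in the annotation, looked up after the data were seen, did not share this difference. Orai3 differed by -0.20, Setd1a by 0.21 and Hsd3b7 by 0.05 on one side, and Zfp668 by 0.11, Zfp646 by 0.08 and Prss53 by -0.25 on the other, of which Zfp668 and Prss53 were under the level filter. Both arrays had the pattern of male tissue. Xist, the X-inactivation transcript, was at 4.45 in the wild-type and 4.39 in the transgenic array, under the olfactory receptor percentile of 5.42. The Y-linked genes Kdm5d (8.04 and 7.97), Eif2s3y (9.32 and 9.64) and Uty (8.09 and 8.09) were well above it.

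Most genes had similar levels in both arrays. Across the 9974 genes that passed the level filter, 95.6% lay within 1.5-fold, the median difference was 0.03, and the middle 95% of differences ran from -0.51 to 0.61. Across these genes, which are not independent replicates, the arrays correlated with r = 0.98. In the transgenic array, 265 genes were higher by at least 1.5-fold and 171 were lower. At 2-fold the counts were 86 and 38, and at 4-fold 15 and 3.

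The 15 genes with the largest positive difference included secreted adipocyte products, ion channel and neuronal genes, and a glutathione transferase. Opn3, which encodes an opsin, was highest with a difference of 3.50 (11.3-fold). Chml, a Rab escort protein whose annotated span overlaps that of Opn3 on chromosome 1, differed by 2.28, and signal of these overlapping genes cannot be fully separated. Lep, the adipocyte hormone leptin, was 9.19-fold higher (3.20, 9.06 against 5.86), and Adipoq, the adipocyte hormone adiponectin, was 4.17-fold higher (2.06). Nnat, which encodes neuronatin, differed by 2.75. Scn2a, a voltage-gated sodium channel, differed by 2.88 on its brightest probe set, and all 14 of its probe sets were higher, by 1.57 to 3.50. Gstm5, a mu-class glutathione transferase, reached 13.19 in the transgenic against 10.52 in the wild-type array, a 6.36-fold difference. Related mu-class genes are similar in sequence, so cross-hybridisation leaves its share of the signal uncertain. Gdf11, a secreted factor of the TGF-beta family, was 4.53-fold higher (2.18). The others were Fsd1l (2.94), the vault RNA Vaultrc5 (2.85), Fam171b (2.83), Tmc6 (2.25), Calml4 (2.16) and Heca (2.12), with Stx4a completing the group. The wild-type levels of Lep, Opn3 (6.38), Tmc6 (6.35) and Nnat (6.58) were under the level filter of 6.79, so the folds of these genes rest on a dim value and are uncertain.

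Among the 15 genes with the largest negative difference, Slc40a1, the iron exporter ferroportin, was 4.99-fold lower in the transgenic array (7.62 against 9.94). Ostn, which encodes the muscle-secreted peptide musclin, was 4.44-fold lower (8.03 against 10.18). The serine protease gene Htra4 differed by -2.05, the small GTPase gene Rasd2 by -1.99 and the non-classical MHC class I gene H2-T10 by -1.96. H2-T10 belongs to a family of near-identical genes and its value is uncertain. Neto2, an auxiliary subunit of kainate receptors, differed by -1.93, and Kcng4, a potassium channel subunit, by -1.70. Snai3 (-1.60), Lgi1 (-1.49), Abhd18 (-1.41), Lrrc52 (-1.37), Dkk2 (-1.30), a secreted Wnt pathway regulator, and Agbl1 (-1.26) followed. Mettl21c, a protein lysine methyltransferase of muscle, was bright in both arrays and 2.69-fold lower (10.06 against 11.49). Spns2, a sphingosine 1-phosphate transporter, differed by -1.23.

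**Figure D1:**
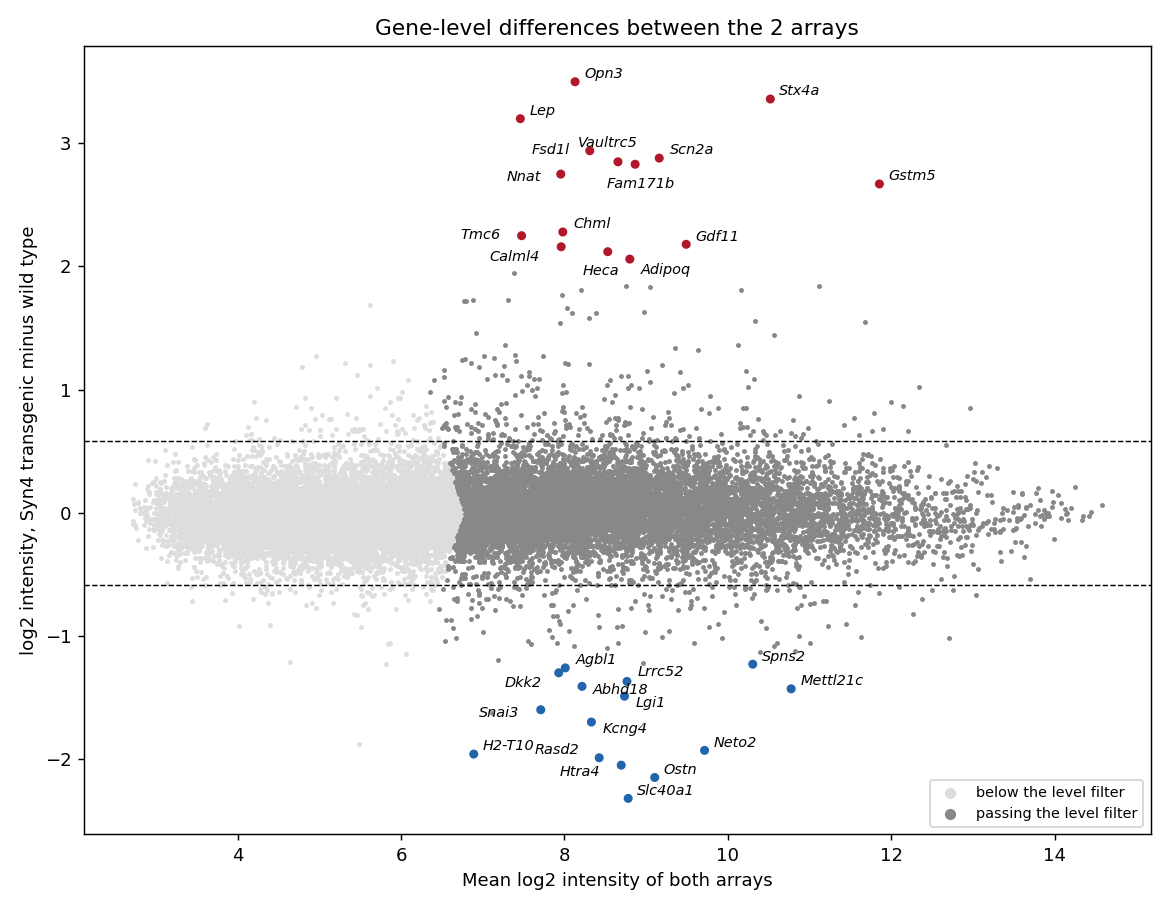
Difference in log2 intensity between the transgenic and the wild-type array (y axis) against the mean log2 intensity of both arrays (x axis), 1 point per gene. Dashed lines mark 1.5-fold, dark points pass the level filter, and red (higher) and blue (lower) points with labels are the named genes with the largest differences. Stx4a stands at a difference of 3.36, close to Opn3 at 3.50.

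Apart from Stx4a, the measured genes of vesicle exocytosis and GLUT4 trafficking differed little. None of the other 30 measured members of that list reached 1.5-fold, and their differences ran from -0.46 to 0.49 with a median of -0.03. Vamp2 and Lnpep, also on that list, were not among the measured genes, so nothing can be said about them. Slc2a4, which encodes GLUT4, differed by -0.35, the SNARE partner gene Snap23 by 0.05, Vamp3 by 0.03 and Stxbp3 by 0.33. These genes, Vamp2 and Lnpep were chosen for naming after the values were seen. The Rab GTPase-activating proteins that restrain GLUT4 vesicles lay at the ends of the range, with Tbc1d4 at -0.46 and Tbc1d1 at 0.49, and the endosomal SNARE gene Vamp8 was at -0.42. With Stx4a included, the list's median of -0.02 lay at percentile 23.5 of level-matched random lists. Its mean of 0.14, at percentile 98.0, had the opposite sign and includes the 3.36 of Stx4a, and the median of the members that passed the level filter was 0.04. Of 30 genes of insulin and IGF1 signalling, 19 were above 0 and 11 below, and none reached 1.5-fold. The receptor gene Igf1r (0.54) and the transcription factor gene Foxo1 (0.49) were highest, and Igfbp5 (-0.43) and Trib3 (-0.36) lowest. The median of 0.12 lay at percentile 97.1, just inside the limit, and passed it in 5 of 8 alternatives, loess and quantile scaling among them.

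Lists of oxidative phosphorylation, fatty acid oxidation and glycolysis genes stood apart as lower in the transgenic array, and most of their members differed by less than 1.5-fold. Of 37 genes of oxidative phosphorylation, 36 were lower, with a median of -0.16 that lay below all 10000 matched random lists. Sdhd and Atp5o (both -0.40) were lowest, Atp5d was at -0.02 and Cycs at 0.02, and none reached 1.5-fold. Of 31 genes of fatty acid uptake and oxidation, 29 were lower, with a median of -0.26, again below all random lists. Plin5, which coats lipid droplets (-0.64), and Lpl, lipoprotein lipase (-0.60), passed 1.5-fold. Ppard was at 0.04 and Lipe, hormone-sensitive lipase, at 0.51. Of 21 genes of glycolysis and glycogen metabolism, 19 were lower, with a median of -0.20 at percentile 0.05. Pfkfb3, which makes the allosteric activator of phosphofructokinase, was 2.08-fold lower (-1.06), followed by Pgam2 at -0.43. Hk1 (0.02) and Gys1 (0.07) were the only members above 0. Of 23 genes of the TCA cycle and mitochondrial biogenesis, 19 were lower. Idh2 passed 1.5-fold (-0.70), Mfn2 was at -0.27, Gabpa at 0.07 and Opa1 at 0.06, and the median of -0.10 lay at percentile 2.81, inside the limit. It passed the limit with averaged probe sets (percentile 0.585) and with the mean in place of the median (0.885). Lists of lipid synthesis did not stand apart. The median was -0.05 over 18 genes of fatty acid and triglyceride synthesis (percentile 12.6), with a mean of 0.03. Scd1, a desaturase abundant in adipocytes as well, was 1.83-fold higher (0.87), Pparg was at 0.44, Dgat2 at -0.22 and Acly at -0.42. The median was -0.03 over 13 genes of cholesterol synthesis (percentile 22.7), from Fdft1 (-0.44) and Mvd (-0.39) to Sc5d (0.12) and Srebf2 (0.22). Markers of slow fibres were lower and those of white adipocytes higher in the same array, as given next.

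Contractile genes of slow-twitch fibres were lower in the transgenic array, and those of fast-twitch fibres were near equal. Of 15 slow fibre genes, 14 were lower and 9 by at least 1.5-fold. The list median of -0.63 was the lowest of the 35 lists and lay below all 10000 matched random lists. The slow isoforms of myosin light chain (Myl3, -1.02), troponin C (Tnnc1, -1.01), troponin I (Tnni1, 10.37 against 11.37) and troponin T (Tnnt1, -0.90) were each close to 2-fold lower. Myh7, the slow myosin heavy chain, was 1.77-fold lower (11.86 against 12.68). Atp2a2, the slow fibre calcium pump (-0.67), Tpm3, Myl2 and Csrp3 (each -0.63) also passed 1.5-fold. Ankrd2 was at -0.05. Sln, which encodes the calcium pump regulator sarcolipin, was the exception at 0.95, but at 6.10 in the transgenic array it was under the level filter. Of 19 fast fibre genes, 12 were above 0, 6 below and 1 at 0, and none reached 1.5-fold. Their median of 0.03 lay at percentile 78.9. Myh1 (0.36) and Myom2 (0.27) were highest, and Myh2 (-0.15) and Myoz1 (-0.24) lowest.

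White adipocyte markers were higher in the transgenic array, more so than any other list. Of 15 measured markers, 12 were higher, 7 of them by at least 1.5-fold and above the level filter. The median of 0.65 lay above all 10000 matched random lists, and it was 1.12 without the 4 markers that another list holds, an alternative chosen after seeing the data. After Lep and Adipoq, the lipid droplet genes Cidec (1.81, 3.51-fold) and Plin1 (1.62, 3.07-fold) differed most, followed by Retn, the hormone resistin (1.15), Pck1 (1.12) and Slc7a10 (0.86). The 3 markers that were lower, Car3 (-0.54), Gpd1 (-0.51) and, named after its value was seen, Cd36 (-0.13), are also made by muscle fibres and had wild-type levels of 13.97, 13.02 and 12.11. In all, 11 of the 15 markers were at or above the level filter in wild-type muscle. The brown adipocyte list went the other way, with a median of -0.19 over 11 genes (percentile 1.38). Zic1 (-1.04) and Ppara (-0.39) were lowest, and Dio2 (-0.04) and Kng1 (0.08) highest. Only 5 of these 11 passed the level filter, with a median of -0.34, and the list did not stand apart after loess (percentile 2.82) or quantile scaling (2.58), or without genes of other lists (4.39). Other lists also hold 4 of the 11, such as Cox8b (13.78 in wild type), Cox7a1 (13.36) and Fabp3 (12.97). Ucp1 was at 5.23 in the wild-type and 5.04 in the transgenic array, under the olfactory receptor percentile of 5.42. These 4 genes were named after their values were seen. The list median therefore does not read brown adipocytes as such.

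**Figure D2:**
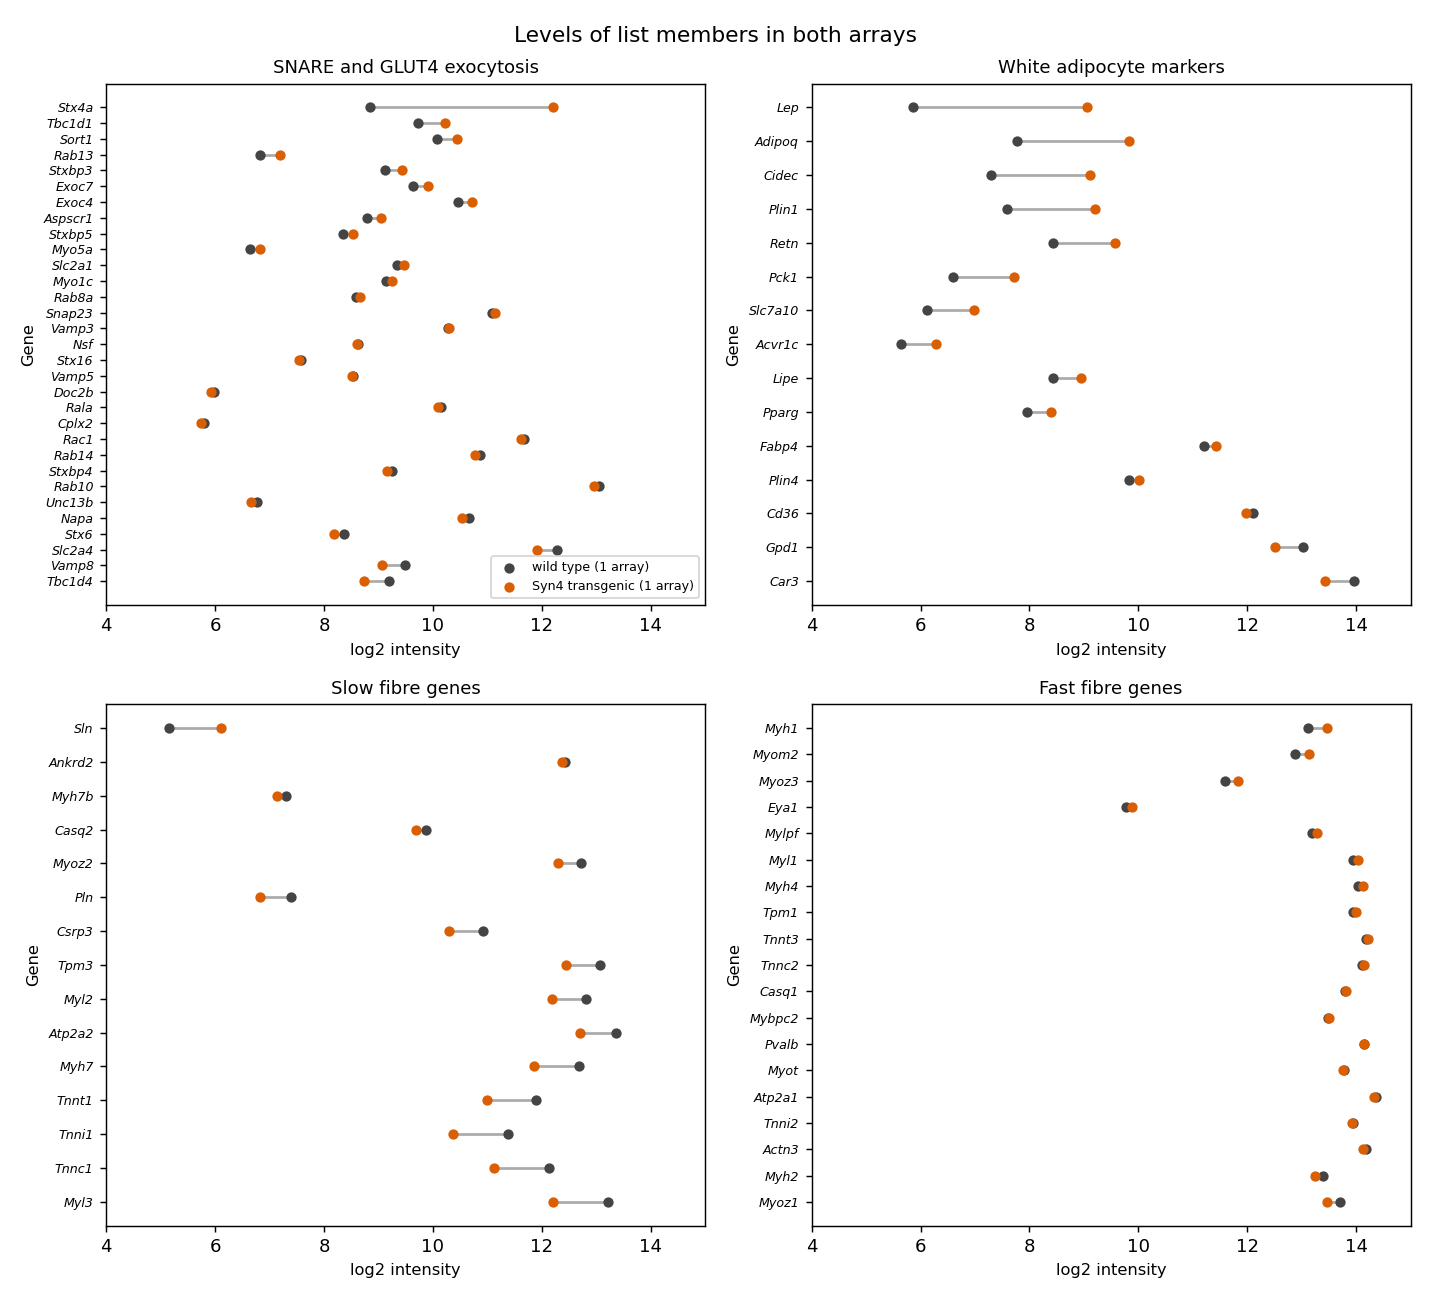
Log2 intensity (x axis) of each measured gene (y axis) of 4 lists in the wild-type array (dark) and the transgenic array (orange), joined by a line. In the exocytosis list Stx4a alone differs by over 1.5-fold, slow fibre genes from Myl3 to Csrp3 are shifted to lower values, and adipocyte genes from Lep to Slc7a10 to higher values.

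Several stromal and nerve marker lists were also higher. Of 22 fibroblast and matrix genes, 20 were higher, with a median of 0.28 above all random lists. Lum, the proteoglycan lumican (0.74), and Lox, lysyl oxidase (0.63), passed 1.5-fold, and Thy1 (-0.15) and Col5a1 (-0.01) were lowest. Of 14 Schwann cell and nerve genes, 11 were higher (median 0.23, percentile 99.96). Only 7 of the 14 passed the level filter, and their median was 0.40. Egr2 (1.08), which is also in the immediate early list, passed 1.5-fold. Ncmap (0.90), Nefl (-0.29) and Gfap (-0.16) were under the level filter. The smooth muscle and pericyte median was 0.17 over 14 genes (percentile 98.4), from Kcnj8 (-0.34) and Notch3 (-0.15) to Myh11 (0.33) and Cnn1 (0.88). The macrophage median was 0.15 over 23 genes (percentile 98.8), from Fcer1g (-0.13) and Adgre1 (-0.12) to Cd74 (0.43) and H2-Eb1 (0.47). With means in place of medians neither list stood apart (percentiles 94.3 and 96.6). Among 20 genes of satellite cells and regenerating or denervated fibres, 14 were higher, with a median of 0.26 above all random lists. Ankrd1 was 3.56-fold higher (1.83), Ncam1 2.20-fold (1.14) and Runx1 2.06-fold (1.04), whereas Actc1, cardiac actin, was 2.17-fold lower (-1.12) and Pax7 was at -0.33. Tendon genes had a median of -0.12 over 13 genes (percentile 2.09), from Chad (-0.57) and Comp (-0.47) to Thbs4 (0.29) and Kera (0.42). That list did not stand apart with filtered genes only (2.85) or without matching on level (5.35). Endothelial genes had a median of 0.00 over 17 (percentile 34.6), from Kdr (-0.44) and Eng (-0.33) to Fabp4 (0.22) and Vwf (0.32). None of the neutrophil and mast cell markers (median -0.07, percentile 31.9, from Cpa3 at -0.71 to Mmp8 at 0.44) and none of the lymphocyte markers (median -0.11, percentile 10.7, from Nkg7 at -0.36 to Gzma at 0.22) passed the level filter. Red blood cell genes (median -0.06 over 6, percentile 25.8, from Bpgm at -0.47 to Slc25a37 at 0.32) and proliferation genes (median -0.05 and mean 0.02 over 18, percentile 35.4, from Aurkb at -0.22 to Ccna2 at 0.66) did not stand apart.

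Genes of stress responses, ageing and protein turnover gave a mixed picture. Of 24 immediate early genes, which respond to acute stimuli and handling, 18 were higher, with a median of 0.23 at percentile 99.99. Egr1 was 2.31-fold higher (1.21), Ccn1 2.22-fold (1.15) and Egr2 2.11-fold. Fos (0.82), Atf3 (0.74) and Nr4a3 (0.72) also passed 1.5-fold, and Jund (-0.26) and Nr4a1 (-0.21) were lowest. Of 25 interferon-stimulated genes, 20 were higher (median 0.17, percentile 99.8). Ifi27l2a was 2.16-fold higher (1.11). Ifit2 (0.77), Oas1a (-0.17) and Zbp1 (-0.11) were under the level filter. The muscle atrophy and protein degradation median was 0.14 over 18 genes (percentile 98.7, but 93.3 for the mean). The muscle ubiquitin ligase genes Trim63 (0.52) and Fbxo32 (0.47) were highest. Mstn, the growth inhibitor myostatin, was 1.52-fold lower (-0.60) and Ube2b was at -0.11. The other lists did not stand apart. Among 27 longevity and nutrient sensing genes (median 0.02, or -0.005 after quantile scaling, percentile 62.8), Prkag3, the gamma subunit of AMP kinase in fast muscle (0.77), and Terf1, a telomere-binding protein (0.70), passed 1.5-fold, and Ucp3 was at -0.26 and Fgf21 at -0.21. Among 32 antioxidant genes (median -0.04, mean 0.05, percentile 16.1), Gstm1 (1.55), Mt2 (1.01) and Gstm2 (0.85) were higher by 1.5-fold, and Gpx3 (-0.94) and Nqo1 (-0.79) lower. Among 14 cell cycle arrest and senescence genes (median 0.02, mean -0.01, percentile 42.5), Rb1 was at 0.67, Gadd45a at 0.35, Gadd45g at -0.46 and Gadd45b at -0.97. Among 25 cytokine and chemokine genes (median 0.03, percentile 77.4), Tlr4 was at 0.65 and Il15 at -0.60. Among 14 heat shock genes (median 0.09, percentile 88.9, and a mean of 0.17 at percentile 97.7), Hspb1 (0.81) and Dnajb1 (0.68) passed 1.5-fold, with Hspe1 at -0.27 and Hspd1 at -0.08. Among 23 genes of the unfolded protein response (median 0.07, percentile 82.0), Atf3 passed 1.5-fold, Asns (0.67) was under the level filter, and Trib3 (-0.36) and Ddit3 (-0.27) were lowest. Among 25 autophagy genes (median 0.08, percentile 90.4), values ran from Bnip3 (-0.34) and Gabarapl1 (-0.19) to Nbr1 (0.30) and Tfeb (0.37). Among 17 circadian clock genes (median -0.01, percentile 27.6), Bhlhe41 was 1.87-fold lower (-0.90), Ciart was at -0.56, Cry2 at 0.43 and Per1 at 0.54. Among 24 ribosomal protein genes (median -0.03, percentile 38.3), values ran from Rpl10a (-0.27) and Rps3 (-0.23) to Rpl4 (0.20) and Rpl30 (0.40).

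**Figure D3:**
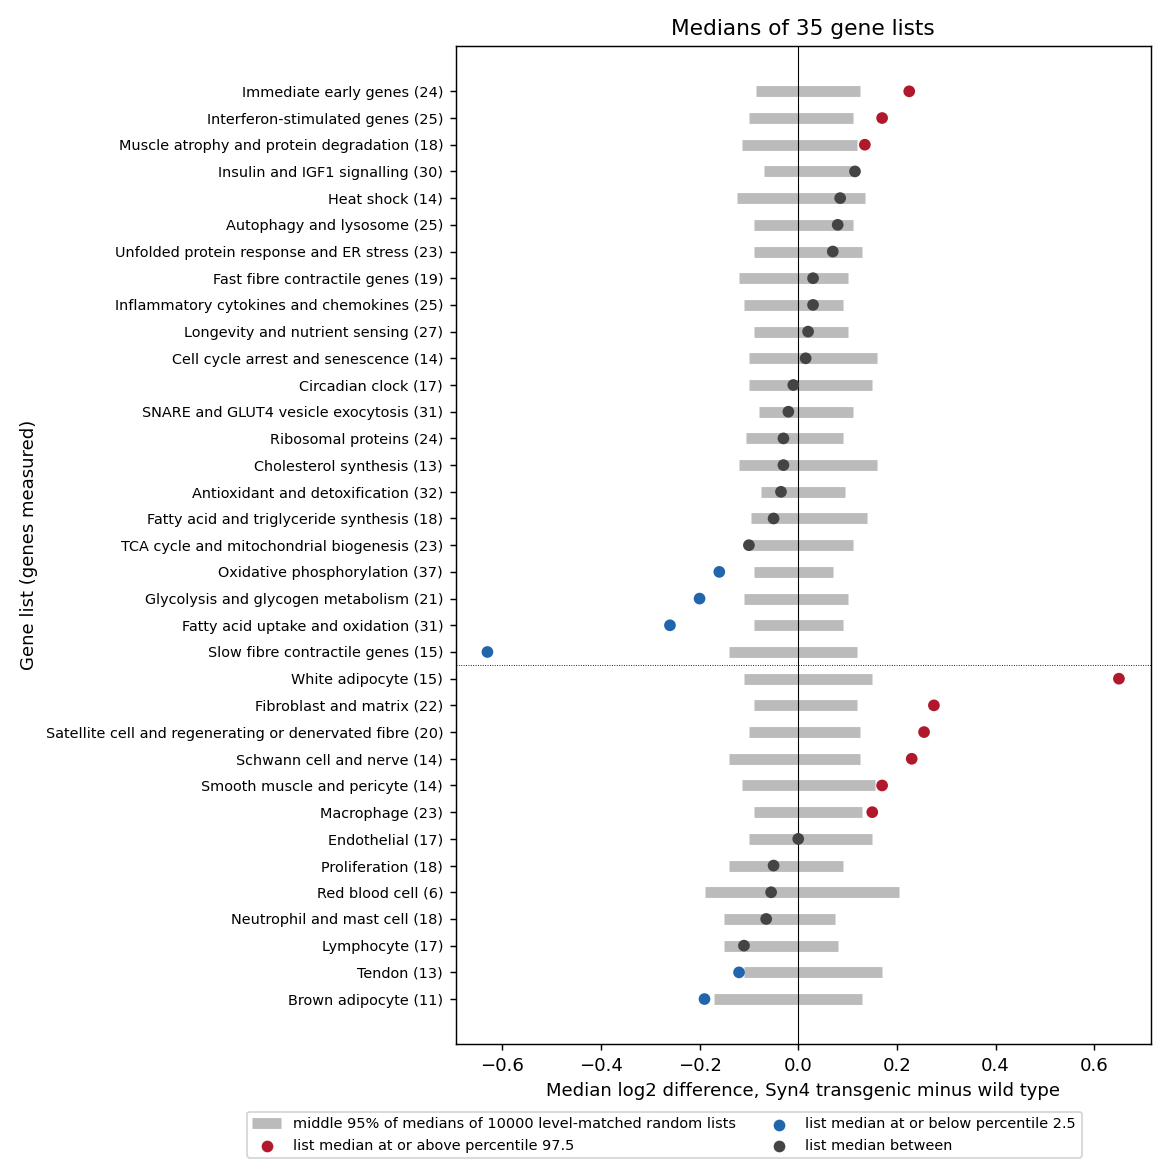
Median log2 difference, transgenic minus wild type (x axis), of 22 pathway lists (above the dotted line) and 13 cell type lists (below it), named on the y axis with the number of genes measured. Grey bars span the middle 95% of medians of 10000 level-matched random lists. In all, 9 list medians (red) stand apart as higher and 6 (blue) as lower, with slow fibre genes at -0.63 and white adipocyte markers at 0.65.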

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

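Both results here were singled out after the data were seen, because they come from probe sets that carry no gene name in the annotation used and so enter no comparison above. One such probe set, number 10472860, had a log2 intensity of 10.76 in the transgenic array against 6.41 in the wild-type array, a difference of 4.35 that exceeds that of every named gene, Stx4a and Opn3 included. Of 3109 unnamed probe sets that passed the level filter, 201 were higher by at least 1.5-fold in the transgenic array and 83 were lower. Some of them repeat each other: 7 of the 201 shared both values with another, which left 196 distinct pairs of values. No explanation was tested for these signals.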

How the results depend on the processing

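The number of genes higher by 1.5-fold (265) ran from 201 to 350, and that of genes lower by 1.5-fold (171) from 142 to 238, under each filter, probe set summary and scaling tried. The 2-fold threshold gave 86 and 38 by construction. Median centring moved nothing, since the median over all genes was 0, and no gene moved by over 0.11 under the other scalings. The Stx4a difference was 3.36, 3.35 after loess and 3.335 after quantile scaling. Of the named genes tried under the scalings, Atp5d alone changed sign (-0.02, and 0.03 after loess), and no list that stood apart did, whereas some lists near 0 changed sign (longevity genes at -0.005 after quantile scaling, red blood cell genes at 0.035 with filtered genes). Ranking by the difference over the local spread kept 15 of the 15 named higher genes and 14 of the 15 named lower genes. Of the 15 lists that stood apart, 12 to 15 did so under each alternative. The brown adipocyte list was inside the limits after loess (percentile 2.82), quantile scaling (2.58) and without genes of other lists (4.39), and the tendon list with filtered genes (2.85) or without matching (5.35). Taking means ended the calls of the macrophage (96.6), atrophy (93.3) and smooth muscle (94.3) lists. Means were 0.14 for exocytosis, 0.0311 for fatty acid synthesis, 0.045 for antioxidant genes, 0.17 for heat shock, 0.33 for immediate early genes, 0.23 for interferon-stimulated genes, -0.52 for slow fibre, 0.84 for white adipocyte and 0.0194 for proliferation genes, and the exocytosis, heat shock and TCA cycle (percentile 0.885) lists then stood apart. With filtered genes only, medians were 0.04 for exocytosis, 0.285 for immediate early, -0.34 for brown adipocyte, 0.40 for Schwann cell and 0.03 for proliferation genes. Without genes held by another list, an alternative chosen after seeing the data, they were 1.12 for white adipocyte, 0.16 for Schwann cell and 0.18 for satellite cell genes. Apart from the construction of the 2-fold and filtered settings, the cause of these shifts was not tested. No paired analysis was possible because each group had 1 array, and no array could be left out for the same reason. Depth in the sense of read counts does not apply, and the lymphocyte, neutrophil and proliferation markers were mostly too dim for a difference to be read.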

Other observations

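The genes in the next paragraph, and further on Plin4, Kmo, Fh1, Wdr64, Pld5, Cep170, Sdccag8 and the members named from the second lists, were chosen after their values were seen. The second adipocyte and slow fibre lists were written after the first lists' results but before their own values were seen, and the other tests here were chosen after the results they bear on were seen.

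Some mu-class glutathione transferase genes, whose enzymes conjugate glutathione to electrophiles, were higher: Gstm5 by 2.67, Gstm1 by 1.55, Gstm3 by 1.04 and Gstm2 by 0.85. Others differed little, with Gstm4 at 0.10 and Gstm7 at -0.04, and Gstm6 (0.30) was under the level filter. Their sequences are similar, so the probe sets do not give independent values. The adjacent decoy receptor genes Tnfrsf23 (1.58) and Tnfrsf22 (1.09) were also higher together. Single genes of secreted proteins that were higher included Hp, haptoglobin, by 1.77, Serpina3n by 1.66, Pon1 by 1.18, and the complement genes C4b by 1.09 and Cfb by 0.61; no list of such genes was tested. Eda2r, a receptor of the TNF receptor family, was higher by 1.63, and Cilp, a matrix protein, by 1.81. Prox1, a transcription factor of slow fibres, was lower (-0.72). Within the list of satellite cells and regenerating or denervated fibres, Chrna1 was at 0.50, Myh8 at 0.35, Gadd45a at 0.35, Musk at 0.28 and Chrnd at 0.09, and Myog (0.00) and Chrng (-0.21) were under the level filter.

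White adipocyte markers had a median difference of 0.65, or 1.12 without the 4 that another list holds, and a hypothesis is that the transgenic sample held more white adipose tissue. A second list of adipocyte genes, of which 19 were measured, had a median of 0.36 and lay at percentile 100 of matched random lists, which is consistent with that hypothesis, from Lgals12 at 1.27, Orm1 at 1.22 and Aoc3 at 1.04 to Aqp7 at -0.24, while 12 of the 19 passed the level filter and Tshr (1.23), Nat8l (0.00), Ffar4 (0.05) and Hcar1 (-0.37) did not. A general loss of muscle fibre RNA that raises every other cell type alike is argued against. The adipocyte median exceeded the endothelial median by 0.65 (bootstrap 95% interval over genes 0.20 to 1.60). This comparison was chosen with both medians known and covers only an equal rise. A smaller general rise beside the adipocyte one was not tested. Medians of fibroblast (0.28), Schwann cell (0.23), smooth muscle (0.17) and macrophage (0.15) lists were higher. Other medians were not, such as endothelial (0.00) and tendon (-0.12). The abundant adipocyte transcripts Fabp4 (11.20 in wild type, difference 0.22) and Plin4 (9.83, 0.18) were little higher. Their level in wild-type muscle would hide a small added share on the log2 scale, so they do not decide the adipose hypothesis. In wild-type muscle, 11 of the 15 markers were at or above the level filter. Whether the transgenic sample held more fat at all, through dissection or in the muscle itself, or whether the genotype acts on these genes, which was not tested, stays open, since each genotype has 1 array.

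Slow fibre genes had a median difference of -0.63. Dilution of all muscle RNA by other tissue is argued against as the whole of this difference. The fast fibre median lay 0.66 above the slow fibre median (bootstrap 95% interval over genes 0.39 to 0.91). Several fast fibre genes, such as Atp2a1 (14.36 in wild type), were near that array's highest value of 14.80, where a loss may be hidden. Fast genes about as bright in wild type as Myl3 (13.22, difference -1.02) were not lower alike. Myh1 (13.11) was at 0.36, Mylpf (13.19) at 0.09 and Myh2 (13.40) at -0.15. A partial dilution is not excluded. Atp2a1 and Mylpf were named after their values were seen. A trend of the difference with brightness is also argued against, because the trend that loess removed was at most 0.06 for any gene and left the slow fibre median at -0.61, and because -0.63 lay below all 10000 random lists of like brightness, whose middle 95% ran from -0.14 to 0.12. A second list of 9 slow fibre genes had a median of -0.31 at percentile 0.035, with Ldhb at -0.92, Pdlim1 at -0.62 and Bdh1 at -0.61 but Mb at 0.00 and Mybpc1 at 0.06. A lower share of slow fibres in the transgenic sample would give this result. Lower expression of these genes within the fibres would give it too, and transcript levels alone cannot tell them apart. Either may reflect which muscles were taken or the mice themselves, and 1 array per genotype cannot separate these.

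Genes that differed by 1.5-fold in the same direction lay next to each other in 24 pairs, against 10 in the median of 10000 random placements (middle 95% from 4 to 16, highest 23). Some of these pairs were overlapping genes or had symbols that share their first letters, as members of a family do. Without them 14 pairs remained, against a random median of 9 and a middle 95% of 4 to 15. As many were given by 719 of the 10000 placements, so the number of remaining pairs cannot be told apart from chance. This count ignores the size of the differences. Of the genes with the largest positive differences, Fam171b lay between Itgav (0.66) and Calcrl (0.59). Fsd1l adjoined Slc44a1 (0.85) and Vaultrc5 adjoined Diaph1 (0.64), all seen after the fact. Stx4a, Lep, Nnat, Tmc6, Gdf11, Calml4, Heca and Adipoq had no such neighbour. Whether the largest differences cluster more than others was not tested. Clustering over longer stretches was not tested. Among the 15 genes with the largest negative difference, Htra4, Rasd2, Neto2, Kcng4 and Snai3 lie on chromosome 8, which was seen after the fact. The pair with the largest differences was Opn3 (3.50) and Chml (2.28), which overlap; of the nearest genes that passed the level filter, Fh1 on one side was at -0.17, and Pld5, Cep170 and Sdccag8, in that order on the other, were at 0.10, 0.34 and 0.63, while Kmo and Wdr64, closer by, were too dim to show a shared difference. Whether that locus differs by a local event, such as a variant or an insertion, was not tested.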
